A study of Mus musculus with 22 samples.

How the data were processed

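Bulk RNA sequencing of mouse liver, thymus and sorted liver CD8+ T cells made up the series, with 22 samples. Values were used for 18 of them, and the 4 liver samples whose labels carry no batch number were not analysed here. The labels write the groups as Aire genotypes with or without TG, and the series title names dnTGFβRII Aire-/- mice. dnTGFβRII mice express a dominant-negative form of the type II TGF-β receptor in T cells. The labels give the strain as C57BL/6 and the same age range for every sample, and the series' design text gives 500000 sorted cells for the CD8+ T libraries. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates of a group were separate animals. By Xist and Y-linked genes each thymus group and the Aire+/+ and TG Aire-/- livers held both sexes. The replicates of those groups were therefore not all from the same animal. Libraries of the same sex within a group cannot be told apart in this way. The p-values thus measure the spread between these samples, part of which may be technical.

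The authors deposited RPKM values (reads scaled to gene length and to the number of mapped reads) in 3 tables of 24786 genes each, 1 for thymus, 1 for the second batch of livers and 1 for CD8+ T cells. STAR 2.5.2b and mm10 are named in the submitters' processing notes. The gene annotation, the counting tool and the reads counted as mapped are not given in the sources used here. The tables hold 20 sets of identical gene values (46 genes in all), such as Sprr2a1 and Sprr2a2, and such genes were not told apart. Genes whose reads can fall on near-identical copies (the Mup, Hba, Hbb, H2-Q, Sprr2 and Cyp families) are uncertain as single genes. No further scaling was applied by default, and tests were run only within a table. Gene positions come from the GENCODE annotation of GRCm38, the assembly that mm10 names.

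Depth was inferred from the step between low RPKM values of 6084 genes with a single annotated transcript. It came to 20300000 to 29600000 reads per library. At the inferred depth 46.8% to 58.1% of low values, up to 5 reads, were whole numbers of reads within a tolerance of 0.1 read, where chance gives 20%. The match was too loose to recover reads, so no count test was used. At those depths 3 reads on a gene of 2000 bases correspond to 0.0507 to 0.074 RPKM, and such floors cover counting error only.

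Thymus and liver were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided) on log2(RPKM + 1). All 3 groups of a table entered 1 fit, without covariates. Genes were kept with an RPKM of at least 1 in at least 3 thymus samples or at least 2 liver samples, and p-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. The pseudocount of 1 understates changes of low genes. The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Gene lists with at least 5 measured members (25 in thymus and 33 in liver) were tested with limma's camera at a preset correlation of 0.01. The estimated correlation and fry, which tests a list by itself and not against other genes, were alternatives. Members past the threshold were counted over all genes tested and adjusted over the list alone.

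Each CD8+ T group had 1 library, so no test was made. Differences of log2(RPKM + 1) were described for genes with an RPKM of at least 5 in one of the libraries compared, and genes differing by at least 1 were counted. The median of each list was placed among 10000 random lists of the same size matched on mean expression.

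Named genes were the check genes (Aire, Tgfbr2, Cd4, Cd8a and Cd8b1), the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap, and up to 4 members of each list that was called or had 3 or more members past the threshold. Where fewer than 10 genes passed, the 5 with the smallest p were named. In CD8+ T cells they were the 10 largest differences each way and list members differing by at least 1. Thymus genes called only without the filter on low values were named after their values were seen. A few genes that the rule names are not reported here.

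The procedure was tested on simulated data made from the real means and spread, with 200 changed genes in each of 20 runs. In thymus it recovered 26.7%, 77.9% and 97.4% of genes changed by 1, 2 and 4 on the log2 scale, with 5.58% false calls. In liver it recovered 5.19%, 56.9% and 91.6%, with 3.21% false calls. The simulated noise was drawn separately for each gene, so these false calls leave out variation shared between genes. Real data can give more: 1 set of unchanged liver groups that kept such variation shared 4379 genes between 2 comparisons. Alternatives were another pseudocount, no filter, 2 other scalings, no trend, only the groups compared, the replicate number as a block, sample weights, a minimum change, each replicate left out in turn and, added later, sex as a covariate. The sex test in liver was labelled by the limits written before it. Whether it can decide was looked at after its value was seen. The called genes differed more between the male and female Aire+/+ libraries than other genes of like level (median ratio 1.43). With the male value set to the depleted mean 0 of the 67 calls were left. A gene with the male Aire+/+ library near the depleted ones could thus hardly be called. A high percentage therefore followed from the choice of called genes, and the test cannot decide on sex. Unchanged groups sharing libraries were simulated 100 times for overlaps. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 prepared tables and figures.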

Results

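RNA from whole thymus, liver and CD8+ T cells sorted from liver was sequenced in bulk, and gene expression was given as RPKM. The thymus set held 3 libraries each of Aire-/-, TG Aire+/- and TG Aire-/- mice. Liver was represented by 2 libraries each of Aire+/+, TG Aire-/- and CD8-depleted TG Aire-/- mice, and liver CD8+ T cells by 1 library each of Aire-/-, TG Aire+/- and TG Aire-/-. Aire drives the expression of tissue-restricted genes in medullary epithelial cells of the thymus, and the series title describes the mice as a model of overlap between autoimmune hepatitis and primary biliary cholangitis. Inferred depths were 22300000 to 29600000 reads in thymus, 20300000 to 22800000 in liver and 21100000 to 22100000 in CD8+ T cells. Between 9761 and 12475 genes reached 1 RPKM per library. The 20 most abundant genes took 7.68% to 12.4% of the summed RPKM in thymus, 23.2% to 35.1% in liver and 13.1% to 20.7% in CD8+ T cells.

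Aire itself (GRCm38 chromosome 10, 78030022 to 78043610, GENCODE vM21) was measured in thymus at 24.2 ± 7.23 RPKM in Aire-/-, 11.6 ± 1.79 in TG Aire+/- and 11.5 ± 7.64 in TG Aire-/- (mean ± SD, n = 3 each). The difference between TG Aire-/- and TG Aire+/- was −0.17 on the log2 scale (SE 0.387, limma adjusted p = 0.935), and its sign turned without TG Aire-/- replicate 2 or 3. A value for the whole gene need not report the loss of an exon, so the genotype is not checked by it. In liver Aire was listed at 0 in Aire+/+ and CD8-depleted libraries and at 0.153 ± 0.21 in TG Aire-/- (n = 2), and in CD8+ T cells it was at or below 0.0006 RPKM. Tgfbr2, whose product the transgene named in the title opposes, stood at 24.1, 17.9 and 18.1 RPKM in the same order of thymus groups, without a call, and the sign between the transgenic groups turned with the scaling. In liver Tgfbr2 rose from 4.59 ± 0.966 in Aire+/+ to 18.2 ± 8.07 in TG Aire-/- (log2 1.73, adjusted p = 0.00929). The CD8-depleted livers held 0.0936 ± 0.132 RPKM of Cd8a (chromosome 6, 71373427 to 71379173), against 6.25 ± 3.54 in TG Aire-/- (log2 −2.64, adjusted p = 0.00249) and 0.19 ± 0.042 in Aire+/+. Cd8b1 fell between the same livers by 2.41 on the log2 scale, and Cd4 fell from 3.23 ± 0.708 to 1.04 ± 0.601 (log2 −1.08, adjusted p = 0.0202).

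The comparison of TG Aire-/- with TG Aire+/- thymus asks what loss of Aire does on the transgenic background. Tff3, a trefoil factor of mucous epithelia (chromosome 17, 31125306 to 31129646), stood at 0.259 ± 0.154 against 2.80 ± 0.38 RPKM (log2 −1.60, SE 0.208, adjusted p = 0.0783). Pyy, a gut hormone (chromosome 11, 102106676 to 102107832), stood at 0.168 ± 0.182 against 3.31 ± 1.32 (log2 −1.85, SE 0.26, adjusted p = 0.0783). Sprr2a1, a cornified-envelope gene (chromosome 3, 92215799 to 92221911), stood at 2.43 ± 0.599 against 12.4 ± 2.49 (log2 −1.96, adjusted p = 0.0783). The antimicrobial lectins Reg3b and Reg3g had log2 differences of −1.61 and −2.44. Among 12568 genes tested limma called 0, with 279 at an unadjusted p under 0.05 (73 higher and 206 lower), and 2 without Aire-/- replicate 1. The median gene differed by −0.14 on the log2 scale.

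All 8 measured members of the fixed list of Aire-dependent self antigens had lower estimates in TG Aire-/- than in TG Aire+/- thymus, with a median log2 difference of −1.10. None fell over all genes, and 3 fell adjusted over the list alone. Camera called the list (adjusted p = 3.52e-11), with adjusted p = 0.397 with an estimated correlation. TG Aire-/- replicate 1 stood apart from its group, with lower values of double-positive thymocyte genes (median log2 difference from the mean of the other 2 libraries −3.23 over 18 genes) and higher values of adipocyte genes (2.95 over 7) and B cell genes (2.07 over 12). Without it 50 genes fell and 0 rose among 12406. The median of the self-antigen list was then −1.63, and 4 of its 8 members fell; lists and genes without that library were looked at after the data were seen. Medians of the medullary epithelium (−0.63), class II (−0.55) and dendritic cell (−0.24) lists were below 0 there too, so a smaller medulla is not separated from a loss of these transcripts within it. Reg3g then fell by 3.35 on the log2 scale, Csn2 (a milk casein) by 1.66, Iapp (islet amyloid polypeptide) by 1.78 and the medullary transcription factor Fezf2 by 1.60. The chemokine Ccl22 fell by 2.08 and the chemokine receptor Ccr7 by 1.37.

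**Figure D1:**
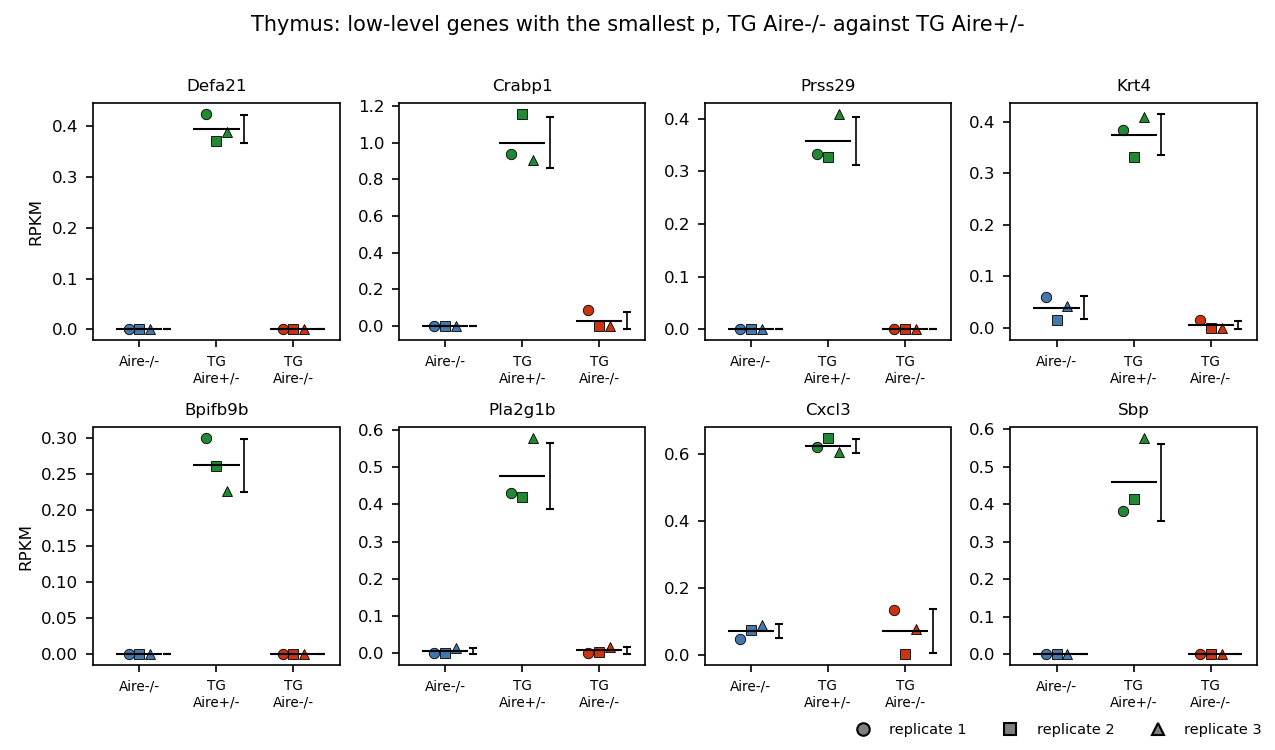
RPKM in single thymus libraries (points) of the 8 genes with the smallest p for TG Aire-/- against TG Aire+/- without the filter on low values, each on its own axis; horizontal bars are group means and error bars are SD of 3 libraries. Every TG Aire+/- value lies above every value of the other groups.

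Of 31 self-antigen genes in the file 8 passed the filter of 1 RPKM. Without it 21083 genes were tested, of which 56 fell and 1 rose in TG Aire-/- against TG Aire+/-, 45 of them genes that the filter had removed. Crabp1, a retinoic acid binding protein (chromosome 9, 54764748 to 54773110), fell from 1 ± 0.138 to 0.0278 ± 0.0481 RPKM. Lypd2 (chromosome 15, 74732247 to 74734329) fell from 1.96 ± 0.156 to 0.199 ± 0.175, and the keratin Krt4 fell from 0.376 ± 0.0404 to 0.00486. Pgc, a pepsinogen of the stomach, averaged 0.998 ± 0.312 in TG Aire+/- and was listed at 0 in TG Aire-/-, as was the defensin Defa21 (0.394 ± 0.0273 against 0). The pancreatic genes Cela3b, Clps and Pla2g1b fell by 0.39, 0.55 and 0.55 on the log2 scale, and the hormone genes Gip and Grp by 0.76 and 1.43. Mean values of the 56 genes in TG Aire+/- had a median of 0.452 RPKM and a highest value of 13.8. Over all libraries 3 reads on a gene of 2000 bases correspond to 0.0507 to 0.074 RPKM, and to more on a shorter gene. Floors of the single genes were not worked out. Genes listed at 0 in both other groups, such as Defa21, added no spread there to the shared fit, so their p-values may be too small. The low-level genes given here were named after their values were seen. Of 29 self-antigen genes tested without the filter, 29 had lower estimates (median −0.29, unadjusted camera p = 1.2e-13, and unadjusted camera p = 0.0103 with an estimated correlation). Without TG Aire-/- replicate 1 and with the filter that last p was 0.00244, also unadjusted. Neither was adjusted over lists, so they cannot be set against the camera adjusted p = 0.397 of the main fit.

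Genes of other thymus cell types moved with TG Aire-/- replicate 1. Members of the double-positive thymocyte list had a median difference of −1.20 between TG Aire-/- and TG Aire+/-, and 0.02 without that library. Rag1, needed for receptor gene rearrangement, averaged 148.9 ± 143 against 331.8 ± 99.8 RPKM. The B cell list had a median of 0.88 (Pax5 6.56 ± 7.35 against 0.587 ± 0.436) and 0.23 without that library. Cytotoxic genes had a median of 0.56 and −0.12 without it, and macrophage genes 0.41 and −0.22. For the medullary epithelium list the median was −0.24 with all libraries, with Krt17 at 50 ± 15.5 against 101.2 ± 10.4. No member of these lists rose or fell with all libraries. Camera called 19 of 25 lists at its preset correlation and 0 with an estimated one, where adjusted p ranged from 0.397 to 0.839.

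**Figure D2:**
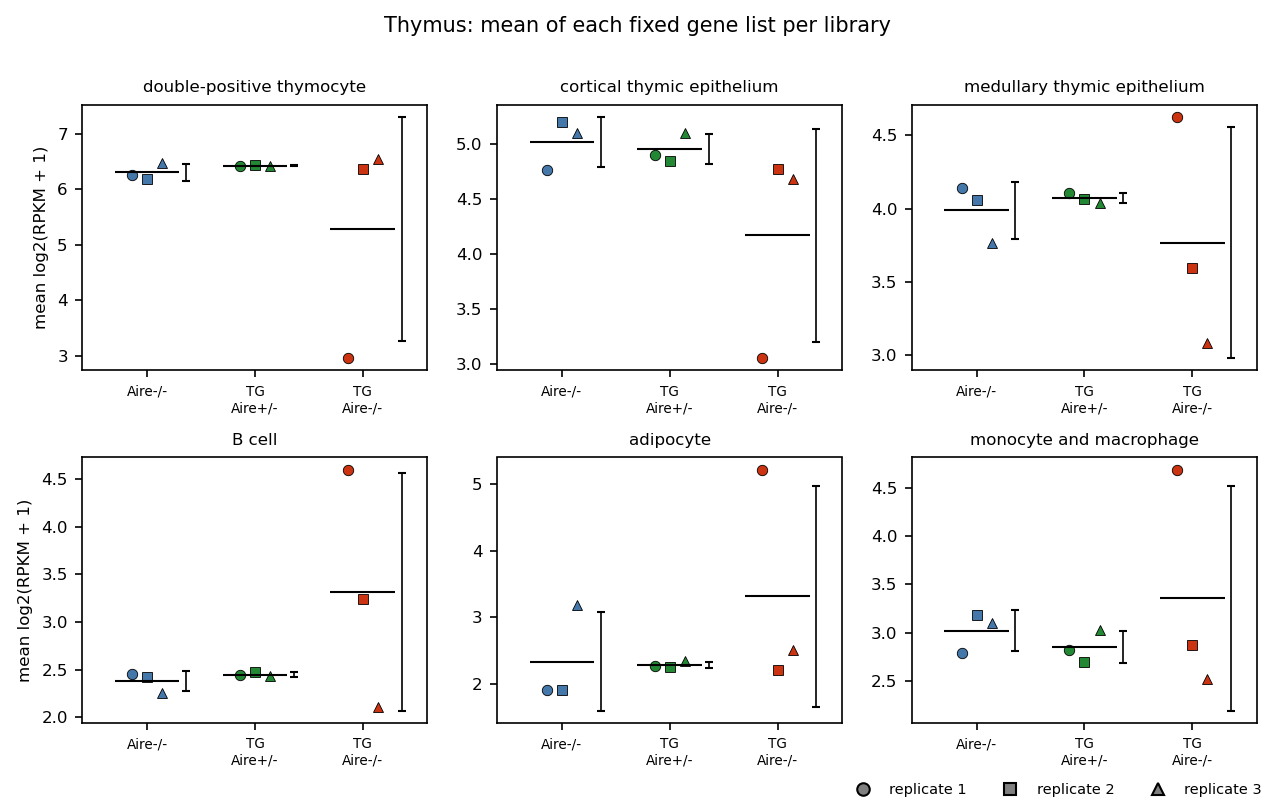
Mean log2(RPKM + 1) of gene lists in single thymus libraries; points are libraries, bars are group means and error bars are SD of 3 libraries. TG Aire-/- replicate 1 lay apart from the other 2 libraries of its group, with lower double-positive thymocyte genes and higher B cell genes.

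Comparison of TG Aire-/- with Aire-/- thymus asks what the transgene adds where Aire is absent. Sprr2a1 and Sprr2a2, which share 1 set of values, fell from 17.4 ± 5 to 2.43 ± 0.599 RPKM (log2 −2.39, SE 0.261, adjusted p = 0.0274) and were the 2 genes called among 12568, with 949 at an unadjusted p under 0.05. The median gene differed by −0.11 on the log2 scale. Vpreb3, a gene of developing B cells, stood at 5.11 ± 2.47 against 0.242 ± 0.108 (log2 2.22, adjusted p = 0.0927). Cyp26a1, which degrades retinoic acid, stood at 0.597 ± 0.225 against 3.70 ± 0.589 (log2 −1.56, adjusted p = 0.12), and the peroxidase Lpo at 0.709 ± 0.457 against 3.88 ± 0.444. The call of Sprr2a1 was lost (0 genes) without Aire-/- replicate 1 or 2, any of the 3 TG Aire+/- replicates, or TG Aire-/- replicate 2 or 3, and 19 genes fell without TG Aire-/- replicate 1. It was also lost with no filter, with both other scalings, with only these 2 groups in the fit, with the replicate number as a block and with sex as a covariate.

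Interferon-stimulated genes had higher estimates in 27 of 31 members in TG Aire-/- against Aire-/- thymus (median 0.56, camera adjusted p = 2.16e-12, adjusted p = 0.562 with an estimated correlation). None rose over all genes and 1 rose adjusted over the list alone. The guanylate-binding proteins Gbp6 and Gbp3 stood at 19.6 ± 3.19 against 9.80 ± 1.9 and at 14.3 ± 12.6 against 3.12 ± 0.194 RPKM. Without TG Aire-/- replicate 1 the median was 0.19. Erythroid genes had a median of 0.81, with Hba-a1 at 279.1 ± 13.3 against 146.2 ± 39.9 and 2 members rising adjusted over the list alone (camera adjusted p = 6.81e-06, adjusted p = 0.562 with an estimated correlation). For self antigens the median was −0.51 (camera adjusted p = 0.0407, adjusted p = 0.655 with an estimated correlation), and Csn2 stood at 13.3 ± 11 against 45.7 ± 4.05. Without replicate 1 Csn2 fell by 2.56 on the log2 scale. With no filter 11 self antigens had lower and 9 had higher estimates (median 0).

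TG Aire+/- against Aire-/- thymus sets mice with 1 working Aire allele and the transgene against mice with neither. Pyy stood at 3.31 ± 1.32 against 0.045 ± 0.0779 RPKM (log2 2.00, SE 0.26, adjusted p = 0.147), Lypd2 at 1.96 ± 0.156 against 0.0257 ± 0.0445 (log2 1.53, adjusted p = 0.147) and Tff3 at 2.80 ± 0.38 against 0.545 ± 0.184 (log2 1.30, adjusted p = 0.341). Psca, a stem cell antigen of stomach and bladder epithelium, stood at 2.19 ± 0.713 against 0.254 ± 0.123. Limma called 0 of 12568 genes, with 118 at an unadjusted p under 0.05, and 4 genes rose without TG Aire-/- replicate 1. With no filter 40 genes rose and 1 fell, 34 of them outside the filter, and 25 of 29 self antigens had higher estimates. The self-antigen list with the filter had a median of 0.61 (camera adjusted p = 1.45e-06, adjusted p = 0.481 with an estimated correlation), and 2 members rose adjusted over the list alone. Interferon-stimulated genes were higher in 30 of 31 estimates (median 0.49, camera adjusted p = 7.09e-18, adjusted p = 0.481 with an estimated correlation), with Xaf1 at 5.66 ± 0.681 against 2.90 ± 1.48 and Irf9 at 15 ± 2.1 against 8.72 ± 1.38.

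The same low-level genes recurred in both thymus comparisons that involve TG Aire+/-. Of the 56 genes that fell in TG Aire-/- and the 40 that rose against Aire-/-, 37 were shared, where independent lists would share 0.106 and 100 simulated data sets without differences shared 0, a value that leaves real effects out and does not measure what the shared libraries add to them. In 54 of the 56 genes every TG Aire+/- value lay above every Aire-/- value. Both comparisons use the TG Aire+/- libraries, and the part of the overlap that this sharing adds cannot be separated.

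In liver, TG Aire-/- against Aire+/+ asks how liver of the double mutants differs from wild type. Values are mean ± SD with n = 2 per group. Ubd, the ubiquitin-like modifier FAT10 (chromosome 17, 37193892 to 37196095), rose from 0.709 ± 0.653 to 286.2 ± 164 RPKM (log2 7.32, SE 1.04, adjusted p = 0.00324). Afp, the fetal plasma protein (chromosome 5, 90490737 to 90508907), rose from 5.48 ± 1.12 to 632.5 ± 155 (log2 6.60, SE 0.288, adjusted p = 0.00041). Cd74, the invariant chain of class II molecules (chromosome 18, 60803848 to 60812652), rose from 20.8 ± 3.27 to 1678 ± 89.6 (log2 6.28, adjusted p = 0.00247). Sprr1a, Fabp4 and Esm1 rose by 6.59, 5.57 and 5.27 on the log2 scale. Cyp1a2 (chromosome 9, 57676937 to 57683703) fell from 226.6 ± 11.7 to 0.934 ± 1.14 (log2 −7.01, SE 0.512, adjusted p = 0.00142) and Cyp2e1 (chromosome 7, 140763739 to 140774987) from 3598 ± 87.6 to 27.6 ± 4.23 (log2 −6.98, adjusted p = 0.00142). Serpina6, the corticosteroid-binding globulin, fell by 6.81.

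All 15 measured pan-T genes rose in TG Aire-/- liver, as did 15 adjusted over the list alone (camera adjusted p = 2.76e-05, adjusted p = 0.452 with an estimated correlation), among them the kinase Lck (6.65 ± 2.12 against 0.362 ± 0.029 RPKM) and Cd3e (5.78 ± 1.67 against 0.247 ± 0.108). All 17 cytotoxic genes rose, with 17 over the list alone (adjusted p = 3.2e-06, adjusted p = 0.384 with an estimated correlation), such as granzyme B (Gzmb, 38.5 ± 10 against 1.77 ± 0.391) and the chemokine Ccl5 (log2 4.18). Of 9 inhibitory receptor genes 8 rose, with 8 over the list alone, including Tigit (log2 2.59) and Pdcd1 (log2 1.73). All 22 macrophage genes rose, with 22 over the list alone (adjusted p = 1.04e-07, adjusted p = 0.511 with an estimated correlation), and the scavenger receptor Marco rose from 8.09 ± 1.45 to 222.6 ± 66.9. Neutrophil genes rose in 13 of 15 (14 over the list alone), with Elane up by 3.23 and Mpo by 3.15 on the log2 scale. Of 6 B cell genes 3 rose, with 4 over the list alone, and camera did not call the list (adjusted p = 0.451, adjusted p = 0.791 with an estimated correlation). None of 7 plasma cell and immunoglobulin genes changed, with 0 over the list alone.

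All 13 class II genes rose in TG Aire-/- liver (13 over the list alone, camera adjusted p = 7.67e-06, adjusted p = 0.478 with an estimated correlation), with H2-Aa at 630.7 ± 65.3 against 9.61 ± 1.84 RPKM. The class II transactivator Ciita rose by 2.02 on the log2 scale. Of 31 interferon-stimulated genes 26 rose, 27 over the list alone (adjusted p = 3.2e-06, adjusted p = 0.539 with an estimated correlation), with Gbp2 at 95.2 ± 3.98 against 2.58 ± 0.989. Of 17 class I genes 12 rose, 13 over the list alone, including the peptide transporter Tap1 (log2 3.12). Chemokine genes rose in 14 of 20 and fell in 2 (15 and 2 over the list alone), with Cxcl9 up from 1.42 ± 0.481 to 80.9 ± 43.1. Fibrosis and matrix genes rose in 24 of 28, with 24 over the list alone (adjusted p = 1.12e-05, adjusted p = 0.539 with an estimated correlation), such as smooth muscle actin Acta2 (42.2 ± 12.3 against 1.88 ± 0.407) and the collagen cross-linker Lox (log2 4.10). Endothelial genes rose in 12 of 13 (12 over the list alone, Eng log2 2.22), erythroid genes in 12 of 14 (13 over the list alone, Slc4a1 log2 3.65) and cell cycle genes in 23 of 29 (27 over the list alone, Mki67 log2 2.37). Handling stress and immediate early genes, which also respond to how tissue is taken, rose in 9 of 19 and fell in 1 (9 and 1 over the list alone, Ier3 log2 4.43, median 1.52). Camera did not call them (adjusted p = 0.29, adjusted p = 0.774 with an estimated correlation), and their part in the other changes was not tested. Of 11 cholangiocyte genes 2 rose, the keratins Krt7 and Krt19 (named after their values were seen), with 1 over the list alone.

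Of 33 drug-metabolising P450 genes 21 fell in TG Aire-/- liver, 22 over the list alone, with a median of −1.73 (camera adjusted p = 6.01e-22, adjusted p = 0.257 with an estimated correlation). Of 24 bile acid genes 14 fell and 1 rose, 17 and 1 over the list alone (adjusted p = 1.34e-13, adjusted p = 0.257 with an estimated correlation). Among them the uptake carrier Slco1b2 fell from 247.1 ± 4 to 22.8 ± 3.54 RPKM, the bile salt carrier Slc10a1 by 2.19 and the bile salt export pump Abcb11 by 2.72 on the log2 scale. Urea cycle and amino acid genes fell in 11 of 22 (11 over the list alone, adjusted p = 3.51e-12, adjusted p = 0.414 with an estimated correlation), including Hpd (log2 −2.93) and Otc (log2 −2.55). Secreted hepatocyte proteins fell in 6 of 22 (3 over the list alone), including coagulation factor F9 (log2 −1.68). Acute phase genes fell in 5 of 25 and rose in 1 (5 and 1 over the list alone), and sex-biased liver genes fell in 3 of 16 (3 over the list alone, camera adjusted p = 6.34e-05, adjusted p = 0.257 with an estimated correlation), among them Elovl3 (log2 −1.56).

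Limma called 4565 of 12231 liver genes between TG Aire-/- and Aire+/+, 3892 higher and 673 lower. The median gene differed by 0.53 on the log2 scale, and with libraries scaled by the median of ratios 1762 genes rose and 1546 fell, so that 53.3% of calls were upward instead of 85.3%. The calls numbered 1270 without TG Aire-/- replicate 2, 1569 without Aire+/+ replicate 1 and 1651 without Aire+/+ replicate 2. With that scaling 4 of the 29 cell cycle genes rose and 14 of the 31 interferon-stimulated genes. Camera called 22 of 33 lists at its preset correlation and 0 with an estimated one.

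**Figure D3:**
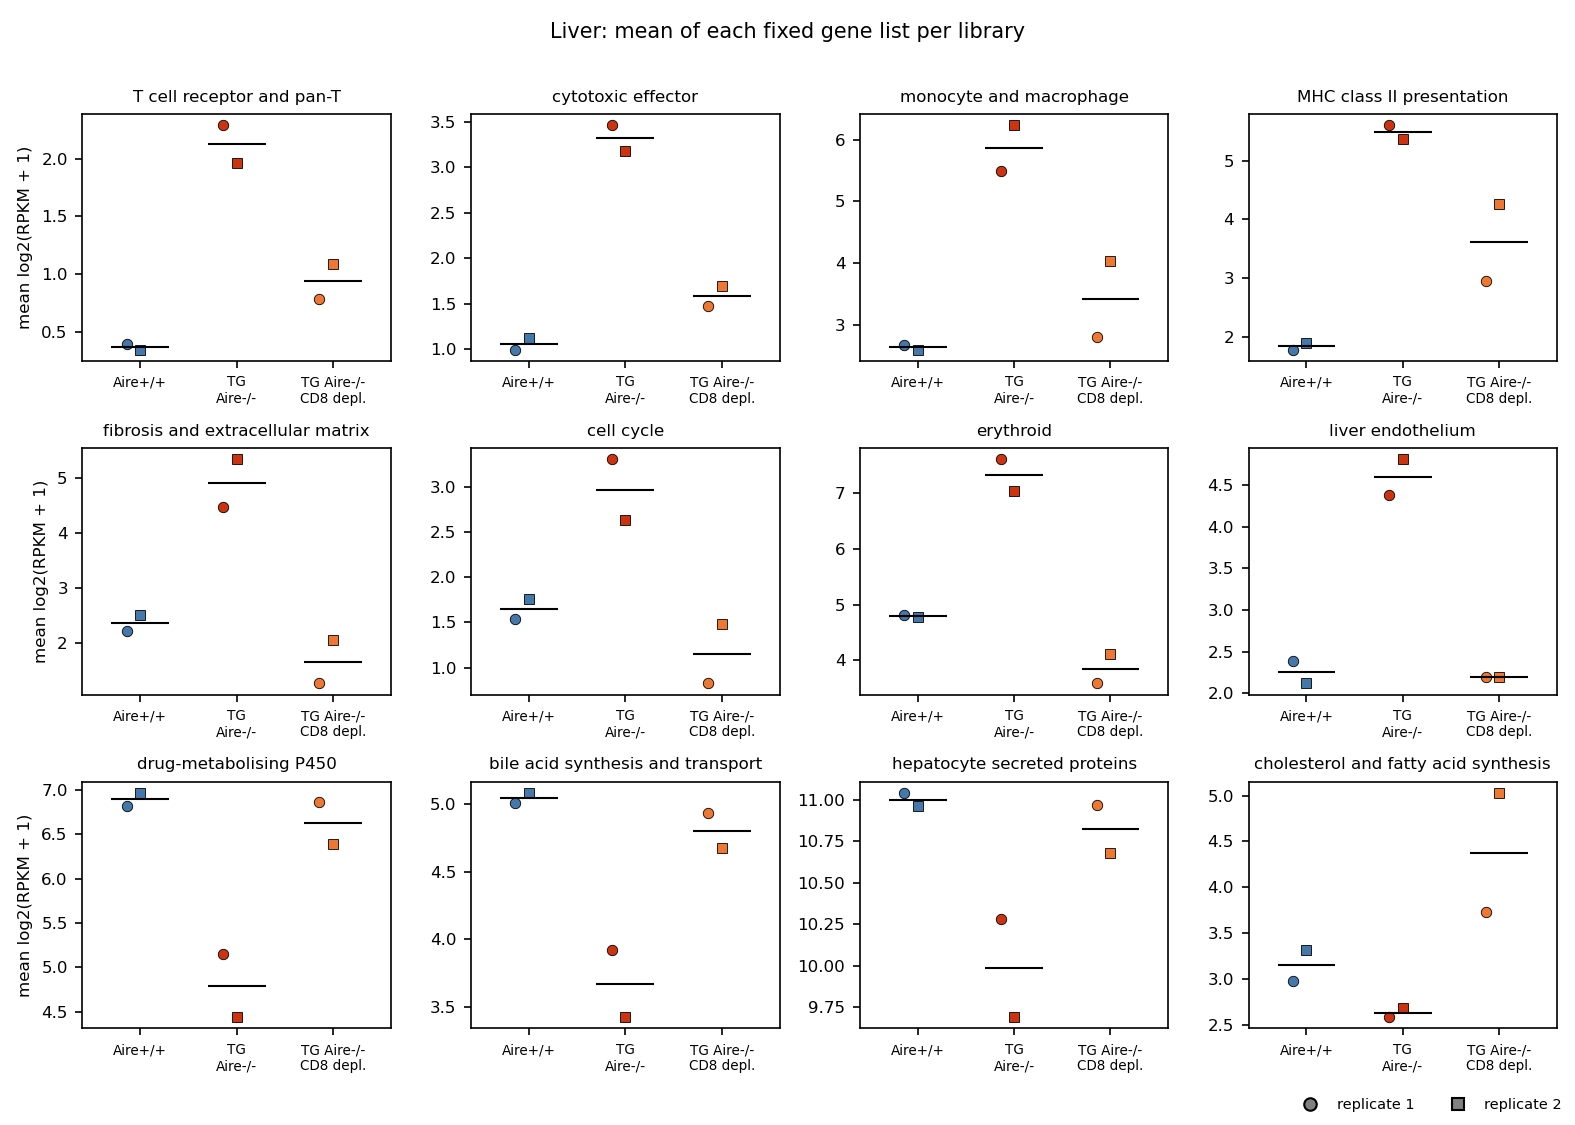
Mean log2(RPKM + 1) of gene lists in single liver libraries; points are libraries and bars are means of 2 libraries per group. The T cell, macrophage, class II and matrix lists were highest in both TG Aire-/- libraries, and the P450 and bile acid lists were lowest there.

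CD8-depleted against undepleted TG Aire-/- liver asks what removal of CD8+ T cells changes in these mice (n = 2 per group). Hamp, the iron hormone hepcidin (chromosome 7, 30942368 to 30944032), rose from 2.2 ± 1.15 to 1825 ± 1400 RPKM (log2 8.95, SE 0.549, adjusted p = 0.000559). Wfdc21 rose from 6.67 ± 0.452 to 960.2 ± 15.8 (log2 6.97, SE 0.264, adjusted p = 7.35e-05), and Scd1, the stearoyl-CoA desaturase (chromosome 19, 44394455 to 44407879), from 4.51 ± 0.877 to 458.9 ± 117 (log2 6.37, adjusted p = 0.000251). The urinary protein gene Mup20, whose reads may be shared with its family, averaged 7.83 ± 3.87 and then 7959 ± 11200 (log2 6.78, adjusted p = 0.0421). Afp fell from 632.5 ± 155 to 1.5 ± 0.0934 (log2 −7.97, SE 0.288, adjusted p = 7.35e-05), and the oncofetal glypican Gpc3 fell by 5.74. Collagen gene Col1a1 (chromosome 11, 94936224 to 94953042) fell from 111.5 ± 18.3 to 2.25 ± 2.58 (log2 −5.38, SE 0.59, adjusted p = 0.00204).

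Matrix genes fell in 26 of 28 members after CD8 depletion, 27 over the list alone, with a median of −3.48 (camera adjusted p = 3.26e-09, adjusted p = 0.53 with an estimated correlation). Acta2 fell from 42.2 ± 12.3 to 0.452 ± 0.317 RPKM, and Sparc by 4.14 on the log2 scale. Pan-T genes fell in 14 of 15 (15 over the list alone, Cd2 log2 −1.76, camera adjusted p = 0.00596, adjusted p = 0.613 with an estimated correlation). Cytotoxic genes fell in 14 of 17 (16 over the list alone, adjusted p = 2.77e-04, adjusted p = 0.422 with an estimated correlation), with Gzmb at 2.85 ± 0.051 against 38.5 ± 10 and perforin (Prf1) down by 2.08. Macrophage genes fell in 21 of 22 (22 over the list alone), such as the red pulp factor Spic (log2 −2.19) and Hmox1 (log2 −3.52). Erythroid genes fell in 13 of 14 (13 over the list alone), with Slc4a1 down by 4.17. Class II genes fell in 11 of 13 (13 over the list alone, Ctss log2 −2.70), interferon-stimulated genes in 16 of 31 (18 over the list alone, Ifit2 log2 −3.09) and class I genes in 8 of 17 (8 over the list alone, Tap1 log2 −2.02). Cell cycle genes fell in 28 of 29 (28 over the list alone), including Rrm2 (log2 −2.78). Handling stress and immediate early genes fell in 11 of 19 (11 over the list alone, Ier3 log2 −3.84, median −1.57, camera adjusted p = 0.198, adjusted p = 0.753 with an estimated correlation), and their library means were 2.945 and 3.844 after depletion against 4.519 and 5.471.

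P450 genes rose in 19 of 33 members and fell in 2 after CD8 depletion, 20 and 2 over the list alone (camera adjusted p = 1.51e-21, adjusted p = 0.233 with an estimated correlation). Cyp2e1 rose to 2525 ± 1250 RPKM (log2 6.38) and Cyp1a2 to 125.1 ± 68.7 (log2 6.05), while Cyp3a16, a P450 of young liver, fell by 3.04. Bile acid genes rose in 12 of 24 and fell in 2, 14 and 2 over the list alone (adjusted p = 6.64e-15, adjusted p = 0.233 with an estimated correlation), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 38.6 ± 15.1 against 3.38 ± 3.67. Cholesterol and fatty acid synthesis genes rose in 15 of 25 (17 over the list alone, adjusted p = 4.8e-19, adjusted p = 0.375 with an estimated correlation), including fatty acid synthase (Fasn, log2 2.59) and Thrsp (log2 5.89). Acute phase genes rose in 11 of 25 and fell in 1 (12 and 1 over the list alone), urea cycle and amino acid genes rose in 10 of 22 (11 over the list alone) and secreted hepatocyte proteins in 4 of 22 (3 over the list alone, F9 log2 1.98). Sex-biased liver genes had higher estimates in 15 of 16 and rose in 5, with 5 over the list alone (median 1.39, adjusted p = 7.48e-11, adjusted p = 0.18 with an estimated correlation). They included Cyp2a4 (150.6 ± 47.5 against 2.475 ± 2.18 RPKM), known as higher in females, and Serpina1e (1532 ± 440 against 224.5 ± 83.6), known as higher in males. Jchain, the joining chain of secreted antibodies, rose from 0.615 ± 0.371 to 18.9 ± 12.6 (log2 3.49, adjusted p = 0.00233).

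Between CD8-depleted and undepleted TG Aire-/- liver 549 genes rose and 4097 fell among 12231. The median gene differed by −0.58, and with scaling by the median of ratios 1283 rose and 1558 fell (45.2% upward instead of 11.8%). Then 17 of 29 cell cycle genes, 5 of 15 pan-T genes, 6 of 31 interferon-stimulated genes and 3 of 13 class II genes fell. Calls numbered 1294 without TG Aire-/- replicate 2, 2243 without CD8-depleted replicate 1 and 2945 with sex as a covariate, both CD8-depleted livers being male by Xist and Y-linked genes. Camera called 20 of 33 lists at its preset correlation and 0 with an estimated one.

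Many liver genes changed in opposite directions in these 2 comparisons. Of the 3892 genes higher in TG Aire-/- than Aire+/+, 3178 (81.7%) were lower after CD8 depletion, and of the 673 lower genes 355 (52.7%) were higher. In the same direction there were 2 and 6 genes. Both comparisons share the TG Aire-/- libraries, which alone gives overlap: 100 simulated sets without differences shared 73.4 genes on average in the first direction, with a highest value of 4379 and 1 set sharing as many. In the second direction the simulated mean was 62.9 and 2 sets shared as many. Across genes the 2 sets of log2 changes correlated with r = −0.825, where simulated sets averaged −0.407 and reached −0.999, and genes are not independent replicates. Their covariance was −0.904, below all simulated sets (mean −0.0879, lowest −0.792). The simulation gave every library the spread averaged over the 3 groups. The shared TG Aire-/- libraries varied more than Aire+/+ (sample weight 0.521 against 3.11, a lower weight meaning more spread). Simulated covariances may therefore be too near 0, so lying below them does not separate a real reversal from shared noise. The overlap was 694 without TG Aire-/- replicate 2, 1275 and 1350 without Aire+/+ replicates 1 and 2, 1707 without CD8-depleted replicate 1 and 1244 with scaling by the median of ratios.

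**Figure D4:**
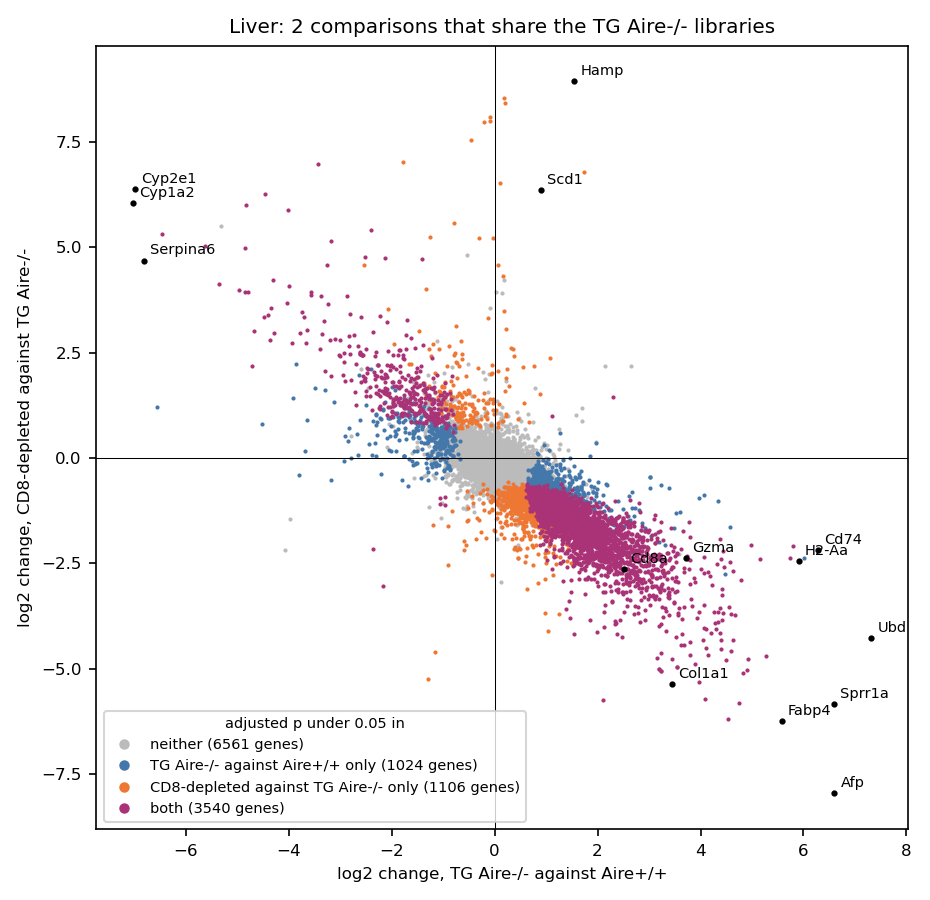
Log2 changes of 12231 liver genes, TG Aire-/- against Aire+/+ on the horizontal axis and CD8-depleted against undepleted TG Aire-/- on the vertical axis; each point is a gene, coloured by the comparisons that called it. Most genes called in both comparisons lie in opposite directions, and both axes share the TG Aire-/- libraries.

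CD8-depleted TG Aire-/- against Aire+/+ liver asks what differs from wild type after depletion. Hamp rose from 0.061 ± 0.0862 to 1825 ± 1400 RPKM (SE of the log2 change 0.549, adjusted p = 0.000783) and Scd1 from 1.98 ± 0.71 to 458.9 ± 117 (log2 7.27, SE 0.313, adjusted p = 0.000379). Pigr, the receptor that carries antibodies across epithelium, rose from 18.1 ± 2.91 to 256.5 ± 55.3 (log2 3.75, adjusted p = 0.00703), and the B cell chemokine Cxcl13 rose by 2.33. Expression of H19, a fetal imprinted RNA (chromosome 7, 142575529 to 142578143), fell from 566 ± 111 to 9.59 ± 2.92 (log2 −5.76, SE 0.487, adjusted p = 0.0053). Cyp3a16 fell from 133 ± 31.1 to 2.63 ± 0.809 (log2 −5.20), Gpc3 by 3.65 and the elastin gene Eln by 3.06.

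Class II genes had higher estimates in 13 of 13 members after depletion against Aire+/+ (median 1.29, camera adjusted p = 3.95e-10, adjusted p = 0.476 with an estimated correlation), of which H2-Ab1 rose (119.8 ± 84.4 against 7.02 ± 0.713 RPKM) and 8 rose over the list alone. Of 31 interferon-stimulated genes 2 rose, 9 over the list alone (median 0.67, adjusted p = 1.05e-09, adjusted p = 0.476 with an estimated correlation), namely the immunity-related GTPase gene Tgtp1 (log2 3.19) and Gbp2 (log2 1.89). Of 25 lipid synthesis genes 2 rose, Scd1 and Elovl6 (log2 2.73), and 7 rose and 1 fell over the list alone. Pan-T genes had a median of 0.58 with 0 called and 5 over the list alone, and Cd3e stood at 1.60 ± 0.66 against 0.247 ± 0.108. Matrix genes had a median of −0.72 with 0 called and 9 falling over the list alone (adjusted p = 1.99e-05, adjusted p = 0.635 with an estimated correlation). P450 genes fell in 2 of 33 (2 rose and 4 fell over the list alone), and 0 of 24 bile acid genes passed over all genes, with 2 rising and 3 falling over the list alone. Of 16 sex-biased genes Cyp2a4 rose (log2 4.79) and Elovl3 fell (log2 −1.41), with 6 and 2 over the list alone (median 0.66, adjusted p = 0.00392, adjusted p = 0.476 with an estimated correlation).

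Between CD8-depleted TG Aire-/- and Aire+/+ liver limma called 67 genes, 27 higher and 40 lower, with 1327 at an unadjusted p under 0.05. There were 14 and 25 calls without Aire+/+ replicates 1 and 2, 13 and 14 without TG Aire-/- replicates 1 and 2, and 141 and 23 without CD8-depleted replicates 1 and 2. Calls also numbered 17 with no filter, 12 with only these 2 groups in the fit and 16 with sex as a covariate. Of the 3178 and 355 genes that changed in opposite directions in the other liver comparisons, 4 and 3 were called here. Camera called 17 of 33 lists at its preset correlation and 0 with an estimated one.

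The sorted liver CD8+ T cells had 1 library per group, so the differences carry no error and no test, and a list is described by its place among random lists. Cd8a stood at 235.9, 259.7 and 172 RPKM and Cd8b1 at 406.6, 500.1 and 415.8 in Aire-/-, TG Aire+/- and TG Aire-/-, against 1.97, 2.67 and 2.00 for Cd4. In the same order Xist stood at 12.2, 28.5 and 11.6 and the Y-linked Ddx3y at 14.3, 0.536 and 2.95. Sex is therefore not separated from the groups. Genes of other cell types differed between libraries: the medians of the neutrophil, monocyte, B cell and erythroid lists were lower in both other libraries than in Aire-/-, though not every member was, such as Cd14 at 6.296, 0.1842 and 7.084 RPKM (S100a8 349.5, 2.99 and 144.2, Lyz2 359, 4.84 and 35.0, Hbb-bs 5815, 66.9 and 54.0).

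TG Aire-/- against TG Aire+/- CD8+ T cells compares mice without and with a working Aire allele on the transgenic background. Aire itself was at or below 0.0006 RPKM in these cells. Of 7701 genes compared, 577 were higher and 635 lower by at least 1 on the log2 scale. Of the 22 genes of handling stress and immediate early response 13 were lower and 0 higher by 1 (median −1.26, percentile 0 of random lists), with Jun at 11.9 against 171 RPKM. Outside that list Nr4a3, a nuclear receptor (chromosome 4, 48045153 to 48086447), stood at 0.657 against 41.0 and Fosl2 at 2.59 against 83.0. Handling stress and immediate early genes also respond to how tissue is taken, and their part in the other differences was not tested. The residency list shares Hspa1a with that list, and the inhibitory receptor list shares Nr4a1. Of 30 interferon-stimulated genes 17 were lower and 0 higher (median −1.49, percentile 0), with Isg15 (chromosome 4, 156199424 to 156200818) at 0.99 against 31.7 and Irf7 at 11.5 against 61.0. NK receptor genes had a median of −1.25 (5 of 16 lower, Klre1 7.25 against 79.8), naive and central memory genes −0.86 (6 of 18 lower, Ccr7 58.4 against 426.2) and TGF-beta response genes −0.56 (4 of 17 lower, Skil 4.71 against 20.6). Effector genes were lower in 8 of 24 and higher in 1 (median −0.48, percentile 0.04), such as Ifng at 64.7 against 186.9, Tbx21 at 19.7 against 58.0 and the late effector marker Klrg1 (chromosome 6, 122270596 to 122282882) at 22.5 against 101.6. The inhibitory receptor list had 5 higher and 4 lower of 14 (median −0.06, percentile 26.82), with Pdcd1 at 15.2 against 5.18 and Lag3 at 26.1 against 7.78, and the lower ones were Cd160 and the nuclear receptors Nr4a1, Nr4a2 and Nr4a3. Cell cycle genes were higher in 8 of 30 and lower in 1 (median 0.42, percentile 99.38), for example Birc5 at 39.7 against 16.1. Neutrophil genes were higher too (median 2.80, 10 of 16), with S100a8 at 144.2 against 2.99.

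TG Aire-/- against Aire-/- CD8+ T cells compares mice with and without the transgene where Aire is absent. Of 7841 genes 982 were higher and 779 lower by at least 1. Stress and immediate early genes were lower in 15 of 22 (median −1.28, percentile 0) and interferon-stimulated genes in 13 of 30 (median −1.40, percentile 0), with Hspa1a at 0.11 against 18.2 RPKM and Irf7 at 11.5 against 36.4. Naive and central memory genes were lower in 11 of 18 (median −1.27), residency genes in 9 with 1 higher (median −1.10, Itgae 1.77 against 18.0) and TGF-beta response genes in 6 (median −0.95, Smad7 7.14 against 25.5). The inhibitory receptor list had 5 lower and 2 higher of 14 (median −0.56, percentile 0.24). Cell cycle genes were higher in 19 of 30 and lower in 0 (median 1.14, percentile 100), with Ccnb1 at 24.6 against 2.99. Effector genes were higher in 7 of 24 and lower in 1 (median 0.37, percentile 75.61, within the range of random lists), among them Gzmk at 211 against 40 and Ccl5 at 3614 against 1226. Among the largest differences upward were S100a4 at 583 against 58.3, Mt1 at 114.6 against 9.22 and Trnp1 at 19.7 against 0.545. B cell genes (median −1.58), neutrophil genes (−1.59) and erythroid genes (−5.55) were lower in TG Aire-/-.

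TG Aire+/- against Aire-/- CD8+ T cells gave 189 genes higher and 225 lower among 7498. Effector genes were higher in 11 of 24 and lower in 0 (median 0.84, percentile 100): Klrg1 stood at 101.6 against 3.18 RPKM, S1pr5 at 35.6 against 1.32, Cx3cr1 at 50.3 against 3.45 and Gzma at 1688 against 575. Cell cycle genes were higher in 11 of 30 and lower in 0 (median 0.88, percentile 100). Inhibitory receptor genes were lower in 4 of 14 and higher in 1 (median −0.36, percentile 0), with Pdcd1 at 5.18 against 20.9 and Tox at 8.79 against 30.1. Interferon-stimulated genes had a median of 0.45 (percentile 99.99), with 1 higher and 1 lower by 1. Neutrophil genes were lower in 15 of 16 (median −3.82), erythroid genes in 8 (median −6.03) and class II genes in 6 of 13 (median −0.85).

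**Figure D5:**
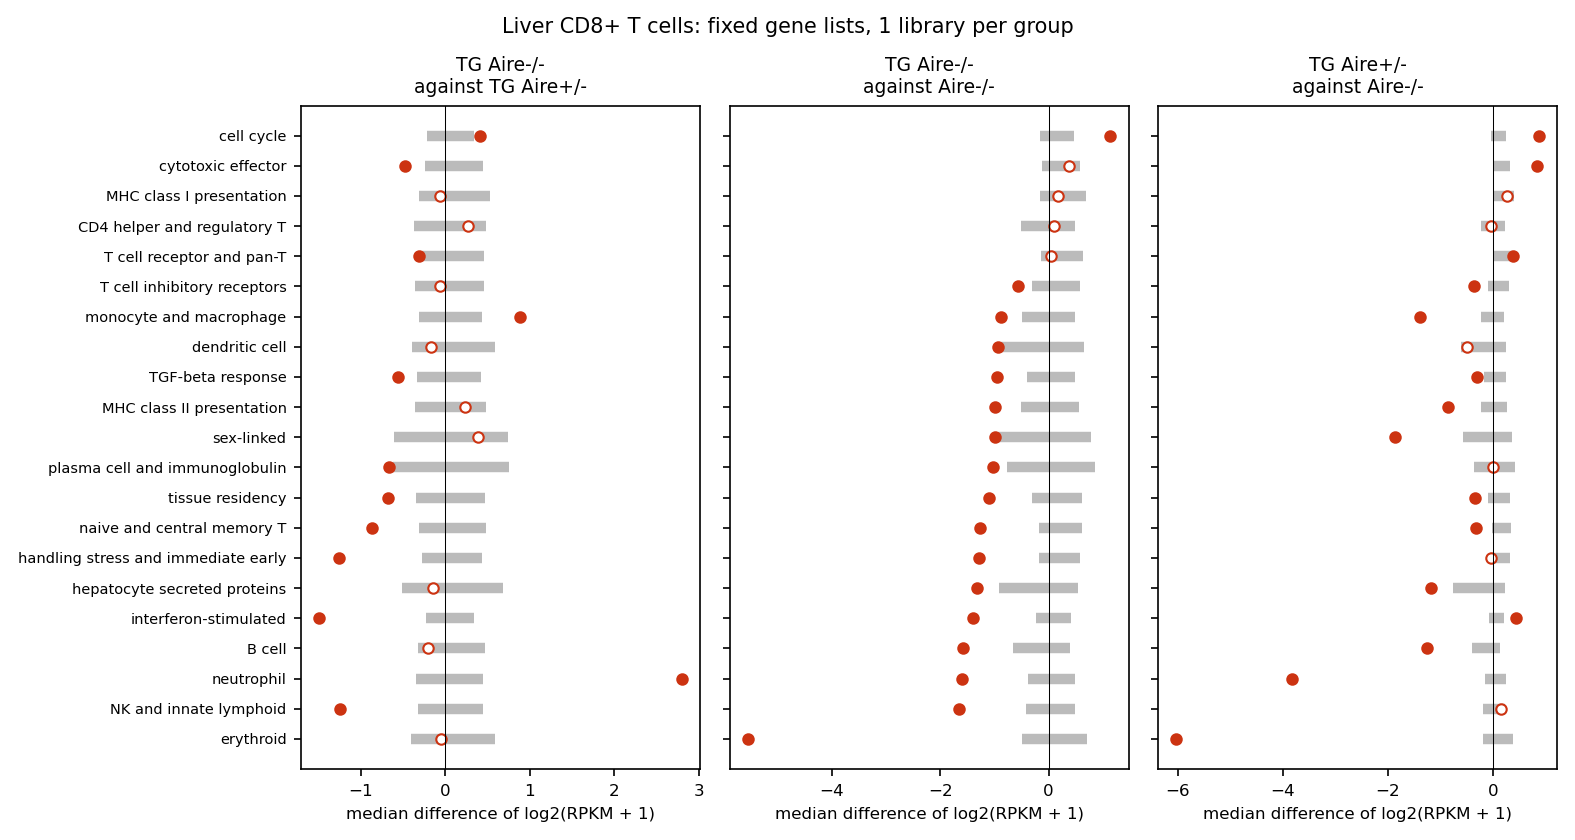
Median difference in log2(RPKM + 1) of gene lists between pairs of single CD8+ T libraries; filled points lie outside the central 95% of 10000 random lists, drawn as grey bars. The interferon-stimulated list lay at −1.49 in TG Aire-/- against TG Aire+/- and at 0.45 in TG Aire+/- against Aire-/-.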

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

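The 3 tests on the thymus library and the scaling test in liver were chosen only after the result was seen. So were the reasons why the scaling test and the sex test cannot decide, and the counts of genes beside the sex test.

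TG Aire-/- thymus replicate 1 lay far from the other 2 libraries of its group, with double-positive thymocyte genes lower by a median of −3.23 and adipocyte genes higher by 2.95. Another tissue taken in place of most of the thymus would lower medullary epithelial genes too, and their median difference was 1.34 (quartiles −0.216 to 1.53), which argues against it. Loss of double-positive thymocytes with all other cells kept would leave cortical epithelium genes at or above the other libraries, and their median was −1.88, but with quartiles from −2.98 to −0.0586 the explanation cannot be told apart from others. A lower share of cortex (thymocytes and epithelium) relative to medulla may account for the pattern, since medullary genes lay 3.22 above cortical epithelium genes. Whether the animal or the piece of tissue sampled gave that share, and whether the genotype had a part, was not tested.

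Most liver genes called between TG Aire-/- and Aire+/+ were higher (85.3%). With libraries scaled by the median of ratios the share was 53.3%, but that scaling itself brings the median gene near 0 (from 0.53 to −0.05), so an even share follows from it, and an effect of abundant genes on the scale cannot be told apart from a broad rise. A lower share of hepatocytes with their genes diluted alike would leave no fall among P450 genes once each library is set relative to its secreted hepatocyte genes, and 13 of 33 still fell (4 rose), which argues against it for P450 genes. Part of the fall may still come from dilution, as the P450 median was −0.72 on that scale and −1.73 without it. Genes switched down after birth (15 measured) had a median of 1.74 in this comparison, where the median gene differed by 0.53. A different maturity of the mice is therefore not separated from the genotype. The genotype stays open as a biological explanation, untested against these.

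Genes such as Scd1 and H19 separated CD8-depleted TG Aire-/- from Aire+/+ liver, and both depleted libraries were male. Sex alone would bring the male Aire+/+ library near the depleted ones. Over the called genes its median distance was 105% of that of the female library (at least 80% in 66 of 67 genes). With its value set to the depleted mean 0 of the 67 would be called, so the percentage followed from the choice of called genes. It cannot decide on sex, and shows only that the male Aire+/+ library also lay apart from the depleted ones in these genes. A part of sex in these changes, or in genes not called, stays open. With sex as a covariate the fit gave 16 calls. The sex-biased list averaged 5.44 and 5.37 in the depleted livers and 3.004 to 4.23 in the others. It holds genes higher in males and genes higher in females, so its mean does not report sex. Male against female libraries averaged 3.935 against 4.23 in Aire+/+ and 3.471 against 3.004 in TG Aire-/-. A different postnatal maturity of the mice cannot be told apart from the treatment: of 15 measured genes switched down after birth 15 had lower estimates, with a median of −0.421 (quartiles −1.24 to −0.218), and 0 passed the test. That median came too near to no change to decide. The labels give every sample the same age range, within which the ages of the groups may still differ. The same genes had a median of 1.74 in TG Aire-/- against Aire+/+ liver. Maturity is therefore not separated in the other 2 liver comparisons either, which share the TG Aire-/- libraries.

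Interferon-stimulated genes in TG Aire-/- against Aire-/- went opposite ways in 2 tissues, with a median of 0.56 in thymus (0.19 without TG Aire-/- replicate 1, adjusted p = 0.562 with an estimated correlation in all libraries) and −1.4 in liver CD8+ T cells, and the difference was not tested. Erythroid genes were higher in thymus by a median of 0.81 and lower in liver CD8+ T cells by a median of −5.55, a difference that was not tested either. In CD8+ T cells the Aire-/- library stood apart (Hbb-bs 5815 RPKM, against 66.9 in TG Aire+/- and 54.03 in TG Aire-/-). The list median was −6.03 in TG Aire+/- against Aire-/- too, so the low value is not particular to TG Aire-/-.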

How the results depend on the processing

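Alternatives with sex as a covariate, and the lists without TG Aire-/- thymus replicate 1, were chosen after seeing the data. Counts of calls are given, and where no cause is named the cause was not tested. In thymus, no filter on low values gave 57, 0 and 41 calls for TG Aire-/- against TG Aire+/-, TG Aire-/- against Aire-/- and TG Aire+/- against Aire-/- (0, 2 and 0 as reported); 45 of the 57 and 34 of the 41 are genes the filter removed. Sample weights gave 8850, 9420 and 8511, where the weighting did not converge and these counts are not usable. Scaling by the median of ratios, quantile normalization, only the 2 groups compared, and sex as a covariate each gave 0 for TG Aire-/- against Aire-/-. Leaving out single replicates gave 0 to 50, 0 to 19 and 0 to 4.

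In liver, TG Aire-/- against Aire+/+ gave 1270 to 5102 calls over left-out replicates. CD8-depleted against undepleted TG Aire-/- gave 2841 with the median of ratios, 2622 with quantile normalization, 2945 with sex and 1294 to 4723 over left-out replicates. CD8-depleted against Aire+/+ gave 17 with no filter, 12 with only the 2 groups (fewer samples), 190 with sample weights, 16 with sex and 13 to 141 over left-out replicates. Genes higher in TG Aire-/- and lower after depletion numbered 1244 with the median of ratios and 694 to 3299 over left-out replicates. A lone library left in a group was assumed to vary like the others. Replicate numbers did not clearly pair the libraries, though a pairing is not excluded. Differences from the group mean were correlated between thymus libraries of different groups. With the same number r ran from −0.183 to 0.766, and with different numbers from −0.757 to 0.55. The block on the numbers gave 0, 0 and 0 calls in thymus, 4341, 4427 and 63 in liver, 3049 shared genes and 99 lists.

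In CD8+ T cells a difference of at least 2 left 181, 277 and 149 genes, and an RPKM of at least 1 gave 757 for TG Aire+/- against Aire-/-, both by construction. Of 98 list calls 0 held with an estimated correlation and fry made 36. Of the named genes 95 passed as reported, and 71 to 112 over left-out replicates. In thymus 3 named values turned, none past the threshold as reported. Over left-out replicates Aire, thymus, TG Aire-/- against TG Aire+/-, ran from −0.636 to 0.116 and Ccr7 from −1.37 to 0.365. For Tgfbr2, thymus, TG Aire-/- against TG Aire+/-, the range was −0.487 to 0.181, with 0.0587 for the median of ratios and 0.0299 for quantile normalization. In thymus 457 of 549 values of named genes stayed the same, 26 were weaker, 57 stronger and 9 reversed, and in liver 1303 of 1397 kept their side of the threshold. Genes named only without the filter have no value in filtered alternatives. Depth limits low genes: 3 reads on a gene of 2000 bases make 0.0507 to 0.074 RPKM, depending on the library, and more on a shorter gene.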

Other observations

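The lists described in this part were picked from the fixed lists only after their values were seen, and the tests of other splits were planned.

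Fatty acid oxidation genes in liver went both ways between TG Aire-/- and Aire+/+, with 3 rising and 4 falling of 25 (3 and 2 adjusted over the list alone). Acot2, an acyl-CoA thioesterase of mitochondria, rose from 4.01 ± 0.411 to 30.5 ± 9.31 RPKM, and Pdk4, which restrains glucose oxidation, from 4.58 ± 0.218 to 62.8 ± 54.5 (n = 2 each). After CD8 depletion 7 of the 25 fell and 0 rose (6 over the list alone), with Acot2 down by 3.01 and Pdk4 by 3.99 on the log2 scale. The median of the list in that comparison was −0.40, and 0.38 with scaling by the median of ratios, so its direction depends on the scaling. Of 14 glucocorticoid-response genes 7 rose and 1 fell in TG Aire-/- against Aire+/+ (7 and 1 over the list alone), with Ddit4 at 69.8 ± 39.6 against 5.92 ± 0.2. After CD8 depletion 8 fell and 1 rose (8 and 1 over the list alone), and the cell cycle inhibitor Cdkn1a fell from 77.2 ± 44.2 to 4.59 ± 0.133.

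Other splits of the 6 thymus libraries of a comparison into 3 and 3 number 10 with the real one, which cannot give a share under 0.05. For TG Aire-/- against TG Aire+/- the real split gave 0 calls and the highest other gave 0, so that 10 of 10 splits gave as many. For TG Aire-/- against Aire-/- the real split gave 2 calls and 2 of the 10 splits gave as many, the highest other giving 404 (Aire-/- replicate 1 with TG Aire-/- replicates 2 and 3 against the rest). For TG Aire+/- against Aire-/- the real split gave 0 calls, 10 of 10 splits gave as many, and the highest other gave 1217 (Aire-/- replicate 1 with TG Aire+/- replicates 1 and 2 against the rest). Splits that call many genes point to a structure of the samples other than their groups. Both of these part Aire-/- replicate 1 from its group. Across genes it correlated at r = 0.9615 and 0.964 with Aire-/- replicates 2 and 3. With TG Aire+/- replicates 1, 2 and 3 r was 0.9901, 0.9887 and 0.9764. With TG Aire-/- replicates 1, 2 and 3 r was 0.9374, 0.9863 and 0.9849. Both comparisons against Aire-/- thymus use this library.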
